A study of Arabidopsis thaliana with 42 samples.

How the data were processed

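RNA from roots and shoots of Arabidopsis thaliana was measured on 42 Affymetrix ATH1 arrays, in 12 groups set by tissue, genotype and zinc supply. Per the labels, total RNA was labelled with biotin and hybridised to 1 array per sample, and the authors named RMA (robust multi-array average) and limma as their tools. Their versions, and the annotation build behind the probe sets, are not given in the sources used here. The deposited values are on the log2 scale: the authors made 1 background-corrected and between-array normalised log2 value per probe set (RMA), with no centring of genes. All 42 arrays had nearly equal quantiles, as quantile normalisation leaves them, with array medians from 6.87 to 6.99 and values from 3.4 to 14.78 on the log2 scale. The raw intensity files were not used, and the signal of the arrays was not computed again. For arrays, it is their number that limits the precision: 4 per root group and 3 per shoot group.

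The table held 22810 probe sets. The 64 Affymetrix control probe sets were left out of the tests and used only to judge RNA quality, and no filter on low values was applied, so that 22746 probe sets were tested. Gene names came from a platform table and from a RefSeq gene table of assembly TAIR10.1, which was used for names and gene order only. Of the tested probe sets, 13513 (59.4%) were paired with 1 gene, 503 with several genes and 8730 with no gene named there. Of the 13513, 13436 matched a RefSeq gene by Entrez identifier and 77 did not. The matched probe sets covered 13286 loci. Probe sets with no name or several names stayed in every test and count. A probe set with no name that is singled out below carries a letter from A to D, in order of mention, and one shared by several genes carries all their names. Of the listed genes, AT3G59930 and AT5G33355 of the bZIP19/bZIP23 target set share a probe set with each other, and NAXT1 of the root tissue markers shares one with AT3G45660. These were left out of the list tests, and that the first pair lay on such a probe set was noticed only after its values were seen.

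Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit and eBayes with default settings). The 24 root arrays and the 18 shoot arrays were fitted separately, each with 1 mean per group and a shared spread per probe set. Comparisons between tissues came from 1 fit of all 42 arrays. A probe set was called when its p-value, adjusted by the Benjamini-Hochberg method over the 22746 probe sets of a comparison, was under 0.05. Every test was two-sided. In all, 21 comparisons were made: low or excess against normal zinc within each genotype and tissue, mutant against wild type at each supply and tissue, the genotype by zinc interactions, roots against shoots in wild type at normal zinc, and the tissue by zinc interactions in wild type. An interaction is the difference between a pair of zinc responses. Tables were prepared with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6, and plots with matplotlib 3.10.9.

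The groups, the comparisons, the gene lists, the rule for named genes and most alternative settings were set before the data were examined. For each zinc comparison in wild type and each comparison of genotypes, the rule named up to 10 genes with the largest rise and up to 10 with the largest fall among called probe sets paired with 1 gene, provided that the values of the groups compared did not overlap. For each other comparison it named up to 5 in each direction, without the condition on overlap for interactions. It added bZIP19 and bZIP23 in every comparison, all measured members of the bZIP19/bZIP23 target set, and up to 4 members of each other list. No probe set was paired with bZIP23 alone, so its transcript could not be read. Names outside this rule are marked as chosen after their values were seen.

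Of the 21 gene lists, most had few members among the probe sets paired with 1 gene. A list was tested as a group when at least 3 members were measured, which held for the iron deficiency response (9 of 32), the plant defensins (8 of 10) and the markers of photosynthetic tissue (4 of 17). Single values are given for the bZIP19/bZIP23 target set (1 of 12), other ZIP/IRT transporters (1 of 7), zinc efflux and sequestration (1 of 13), copper homeostasis (1 of 13), sulfate starvation (2 of 12), metal chelation (1 of 13), oxidative stress and detoxification (1 of 14), flavonoid and anthocyanin synthesis (2 of 11), root hair (2 of 7), circadian clock (1 of 11) and root tissue markers (2 of 10). No member was measured for iron storage and sufficiency, phosphate starvation, zinc-dependent enzymes, heat shock proteins, salicylate and jasmonate defence, suberin and Casparian strip, or cell division. After it was known which genes were measured, 4 lists were added: iron-deficiency marker loci (6 of 8 measured), iron-response bHLH regulators (5 of 5), nuclear photosynthesis genes (14) and chloroplast-encoded photosynthesis genes (43). Every family of gene symbols with at least 8 measured members was tested as well, so that each comparison held 35 lists. Lists were tested with limma's camera at a preset correlation of 0.01, on the probe set with the highest mean per gene, and adjusted over the lists of a comparison. The same test with an estimated correlation was run beside it.

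The models were tested on simulated data with the spread of these arrays and 22746 probe sets, of which 67 were changed 1.5-fold, 67 were changed 2-fold and 66 were changed 4-fold. Between groups, the share recovered ran from 55.2% to 92.5% at 1.5-fold and from 91% to 100% at 2-fold over the comparisons simulated. For interactions it ran from 20.9% to 56.7% at 1.5-fold and from 73.1% to 94% at 2-fold. In a simulated set of 13286 genes, camera recovered a shifted list with an adjusted p of 3.22e-21 on the spread of the root arrays, with 1 other list called, and 6.98e-16 on that of the shoot arrays, with no other list called. The genes were simulated as independent, so this does not show how the preset correlation behaves on genes that vary together.

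The date of each array was read from the original file names quoted in the labels. Roots at low zinc lay on a date of their own, as did shoots at excess zinc, while roots at normal and excess zinc shared a date and shoots at low and normal zinc shared another. Low against normal zinc in roots and excess against normal zinc in shoots are therefore confounded with the date, tissue is confounded with it throughout, and the genotype comparisons are each within 1 date. A constant date effect cancels in the genotype by zinc interactions, but not in the tissue by zinc interactions. Alternatives tried were the replicate number as a block, only the arrays of the groups compared, all 42 arrays in 1 fit, no probe sets from the third of lowest mean, another quantile normalisation, centring of each array, eBayes with trend and robust settings, a call that also needs a fold of at least 2, the mean of a gene's probe sets in the list tests, an estimated correlation in the list tests, and each array left out in turn. Added after the data were seen were fits of 1 array date only, the actin control of each array as a covariate, and fits without 2 arrays whose quality was in doubt, wild type shoot replicate 1 at low zinc for its control probe sets and wild type root replicate 2 at excess zinc for its low correlation with its group. Other splits of the samples were counted for every comparison.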

Results

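Gene expression was measured in Columbia wild type plants and in a bzip19 bzip23 double mutant, which carries T-DNA insertions in genes for a pair of related transcription factors that act in the response of Arabidopsis to zinc deficiency. Plants grew in nutrient solution for 3 weeks at 2 µM zinc sulfate and for 1 further week at 0.05 µM (low), 2 µM (normal) or 25 µM (excess). Each group of roots held 4 arrays and each group of shoots 3 arrays, 42 in all, and each sample pooled tissue of 6 plants from 2 containers. The labels do not say that the replicates of a group came from separate cultures, so the p-values measure only the spread between these samples. Genes could be named for 59.4% of the probe sets, and of the 12 genes in the bZIP19/bZIP23 target set only ZIP9 was among them. The defensin-like genes AT3G59930 and AT5G33355 of that set share 1 probe set, which cannot tell them apart. Every gene named below for the size of its change had no overlap between the values of the groups compared, and adjusted p-values are from limma unless said otherwise.

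The transcript of bZIP19 (AT4G35040), 1 of the pair of genes disrupted in the mutant, was far lower in every mutant group than in wild type. In roots at normal zinc it stood at 9.86 ± 0.13 on the log2 scale in wild type and 4.46 ± 0.19 in mutant (SD, n = 4), a difference of at least 42.2-fold (log2 difference -5.40, SE 0.14, adjusted p = 3.16e-17), and it was at least 37.9-fold lower at low zinc and 34.7-fold lower at excess zinc. In shoots it was at least 20.3-fold lower at low, 21.5-fold at normal and 16.6-fold at excess zinc. Its means in mutant lay above only 10.5% to 18.7% of the probe sets, where background may add to the signal, so these folds are lower bounds and are not compared between supplies or tissues. Folds of other genes whose lower mean was no higher than 4.92, the highest of these means, are given as at least that size. A further gene, AT5G24240, of the phosphatidylinositol 4-kinase gamma family, was lower in all mutant groups as well, by 9.30-fold, 9.77-fold and 13.2-fold in roots at low, normal and excess zinc and by 12.8-fold, 10.8-fold and 12.8-fold in shoots (log2 difference -3.29, SE 0.11, adjusted p = 1.86e-15 in roots at normal zinc). Its difference between genotypes did not pass the test of a change with zinc supply in either tissue, the largest of the 4 interactions being -0.43 in roots at excess zinc (adjusted p = 0.643). These calls held under each alternative tried.

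**Figure D1:**
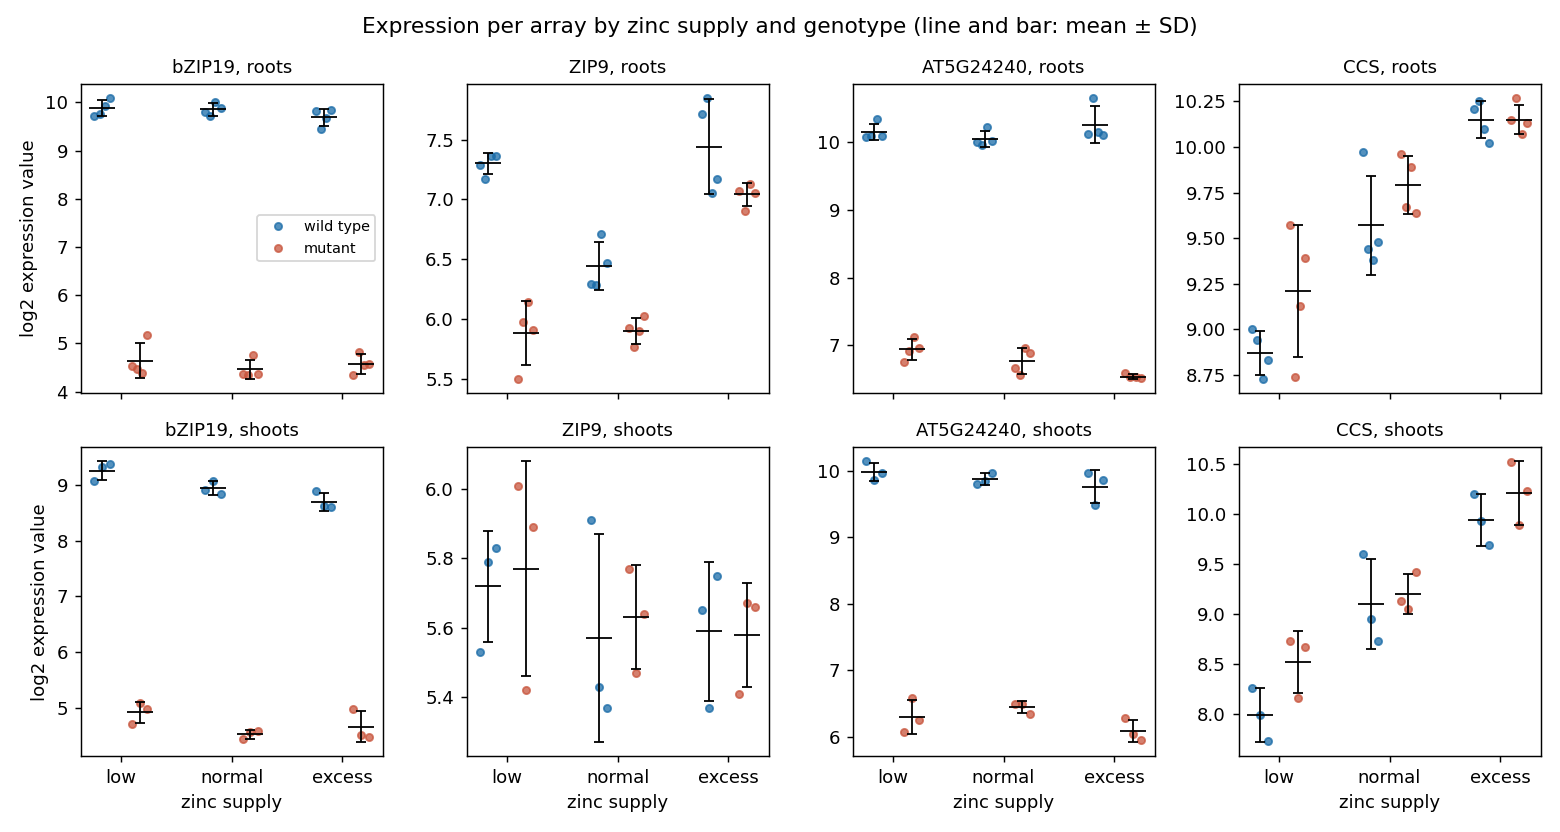
Log2 expression values of bZIP19, ZIP9, AT5G24240 and CCS in each array of roots (top) and shoots (bottom), by zinc supply on the horizontal axis and genotype by colour, with the mean ± SD of each group. The mutant arrays lie far below the wild type arrays for bZIP19 and AT5G24240 at every supply, and ZIP9 in roots is higher in wild type than in mutant at low zinc.

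The first question of the design was how wild type roots respond to zinc deficiency. The zinc transporter gene ZIP9 (AT4G33020) rose 1.81-fold at low zinc, from 6.44 ± 0.20 to 7.30 ± 0.09 (SD, n = 4; log2 difference 0.86, SE 0.15, adjusted p = 0.0112). The probe set shared by AT3G59930 and AT5G33355 rose 5.56-fold (log2 difference 2.48, SE 0.23, adjusted p = 1.44e-06). The largest rise of a gene with its own probe set was that of AT1G71200, which encodes a bHLH factor of the copper response (CITF1), at 7.96 ± 0.40 against 6.27 ± 0.21 (SD, n = 4), a 3.22-fold difference (SE 0.17, adjusted p = 5.64e-06). CCS (AT1G12520), the copper chaperone of superoxide dismutase and the only measured member of the copper homeostasis list, fell 1.61-fold (log2 difference -0.69, SE 0.14, adjusted p = 0.0434), and AT3G15640, a subunit of cytochrome c oxidase, fell 1.46-fold (log2 difference -0.55, SE 0.08, adjusted p = 0.00339). Rises of 1.28-fold to 1.82-fold were found for AT4G04990, AT3G05950, AT4G19370, AT3G44840, AT2G39410, AT1G74440 and BRH1. In all, 30 probe sets changed, 19 up and 11 down, 9 of them by at least 2-fold, and 11 of the 30 were paired with 1 gene. None of the 9 iron deficiency genes passed over all genes tested and 1 fell adjusted over the list alone (limma; camera adjusted p = 0.261), none of the 8 defensins passed and 1 rose adjusted over the list alone (camera adjusted p = 0.804), and the 6 iron-deficiency marker loci all lay below 0 with no member called (camera adjusted p = 0.0231, but adjusted p = 0.646 with an estimated correlation). The groups lay on different array dates, and the count was 19, 17 and 17 without replicates 1, 2 and 4 at low zinc, 66, 15, 16 and 15 without replicates 1, 2, 3 and 4 at normal zinc, 78 without wild type replicate 2 at excess zinc, 164 from the arrays of these groups alone and 70 from all 42 arrays. The call of ZIP9 was lost without replicate 4 at low zinc (log2 difference 0.837) or replicate 2 at normal zinc (0.805), that of CCS without any of the 8 arrays (-0.752 to -0.558) and those of AT4G04990, AT3G05950, AT4G19370, AT3G44840, AT2G39410 and AT1G74440 without most of them. AT1G71200, AT3G15640 and the probe set of AT3G59930 and AT5G33355 kept theirs under every alternative, the fold of at least 2 left aside.

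In mutant roots fewer probe sets were called at low zinc. AT1G71200 rose 2.65-fold at low zinc (log2 difference 1.4, SE 0.17, adjusted p = 0.00055), and its response did not differ detectably between genotypes (interaction -0.28, adjusted p = 1). AT5G05600 rose 1.67-fold (adjusted p = 0.00204), AT3G44840 1.79-fold (adjusted p = 0.00666), AR781 1.89-fold and AT5G12340 1.70-fold. ZIP9 stood at similar means at low and normal zinc, 5.88 ± 0.27 and 5.90 ± 0.11 (SD, n = 4; log2 difference -0.02, adjusted p = 1). The values of CCS (log2 difference -0.58, adjusted p = 0.139) and AT3G15640 (-0.34, adjusted p = 0.156) did not pass. In all 11 probe sets changed, 9 up and 2 down, and of the 30 probe sets called in wild type 27 had the same sign in the mutant, against 59.6% of all probe sets. Both genotypes lay on the same pair of array dates, so a date effect would give the same signs too. The count was 5 without replicate 3 at low zinc, 31, 6 and 5 without replicates 1, 3 and 4 at normal zinc, 21 without wild type replicate 2 at excess zinc and 39 from all 42 arrays. AT3G44840 lost its call without replicate 3 at low (0.791) or replicate 4 at normal zinc (0.733), and AR781 and AT5G12340 lost theirs without most of the 8 arrays.

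At low zinc, the probe set shared by AT3G59930 and AT5G33355 was 43.9-fold lower in mutant than in wild type roots (log2 difference -5.46, SE 0.23, adjusted p = 1.24e-13). ZIP9 was 2.67-fold lower (log2 difference -1.42, SE 0.15, adjusted p = 5.33e-06), while at normal (-0.54, adjusted p = 0.269) and excess zinc (-0.41, adjusted p = 0.168) the difference did not pass. AT1G20380 was 1.98-fold lower (adjusted p = 0.00182) and AT3G12760 1.31-fold lower (adjusted p = 0.00203), and AT5G26270 (2.23-fold) and AT5G59450 (1.31-fold) were higher. In all 19 probe sets differed, 4 higher and 15 lower in mutant. The test of the difference between the genotypes' responses to low zinc called 4 probe sets, each with a smaller rise in mutant, and ZIP9 was not among them (interaction -0.88, adjusted p = 0.828). The largest interaction was that of the probe set shared by AT3G59930 and AT5G33355, which rose 5.56-fold in wild type, from 11.49 ± 0.18 to 13.96 ± 0.08, and stood at 8.30 ± 0.39 and 8.51 ± 0.33 in mutant (SD, n = 4; interaction -2.27, adjusted p = 0.00428). The other 3 could not be named and are called probe sets A to C here, chosen after their values were seen, with interactions of -1.58 for A (adjusted p = 1.98e-06), -1.48 for B (adjusted p = 0.000142) and -0.63 for C (adjusted p = 0.0357). A, B and C were 6.77-fold, 8.44-fold and 2.53-fold lower in mutant than in wild type roots at low zinc. The calls of AT5G26270 and AT5G59450 were each lost without any of 7 of the 8 arrays, and the interaction count ran from 3 to 5 over arrays left out. The call of C was lost in most alternatives and those of the other 3 were kept in all.

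Excess zinc changed far more of the wild type root profile than low zinc, and genes of the iron deficiency response rose together. All 9 measured members rose over all genes tested, and 9 rose adjusted over the list alone (camera adjusted p = 9.8e-23, and adjusted p = 0.00141 with an estimated correlation). S8H (AT3G12900), which makes an iron-mobilising coumarin, rose 12.8-fold from 7.85 ± 1.23 to 11.54 ± 0.76 (SD, n = 4; log2 difference 3.68, SE 0.51, adjusted p = 5.32e-05), and 8.41-fold without replicate 1 at normal zinc. The vacuolar manganese and iron transporter gene MTP8 rose 3.56-fold (adjusted p = 2.04e-06), the beta-glucosidase gene BGLU42 3.36-fold, the iron-deficiency peptide gene IMA1 (AT1G47400) 2.92-fold (adjusted p = 0.000655), F6'H1 of coumarin synthesis 2.32-fold, and the bHLH genes PYE 2.15-fold and BHLH101 at least 2.27-fold. BTSL1 rose by 1.5 and 1.69 on the log2 scale on its 2 probe sets and BTSL2 1.68-fold, both for ubiquitin ligases that act on the iron response. The added list of 6 iron-deficiency marker loci rose in full (camera adjusted p = 7.93e-15, and adjusted p = 0.00142 with an estimated correlation), with AT3G61930 at 8.77-fold, AT5G38820 at 3.69-fold, AT3G07720 at 3.35-fold and AT5G05250 at 3.25-fold. The call of AT1G73120 in this list (log2 difference 1.23, adjusted p = 0.0225) was lost without replicate 1 (1.17) or 3 (1.113) at excess or replicate 1 (1.069) or 2 (1.194) at normal zinc. The 5 iron-response bHLH regulators did not pass (limma, no member called; camera adjusted p = 0.776). ZIP9, a gene of the zinc deficiency response, also rose at excess zinc, 2.01-fold to 7.44 ± 0.40 (SD, n = 4; log2 difference 1.01, adjusted p = 8.97e-05).

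**Figure D2:**
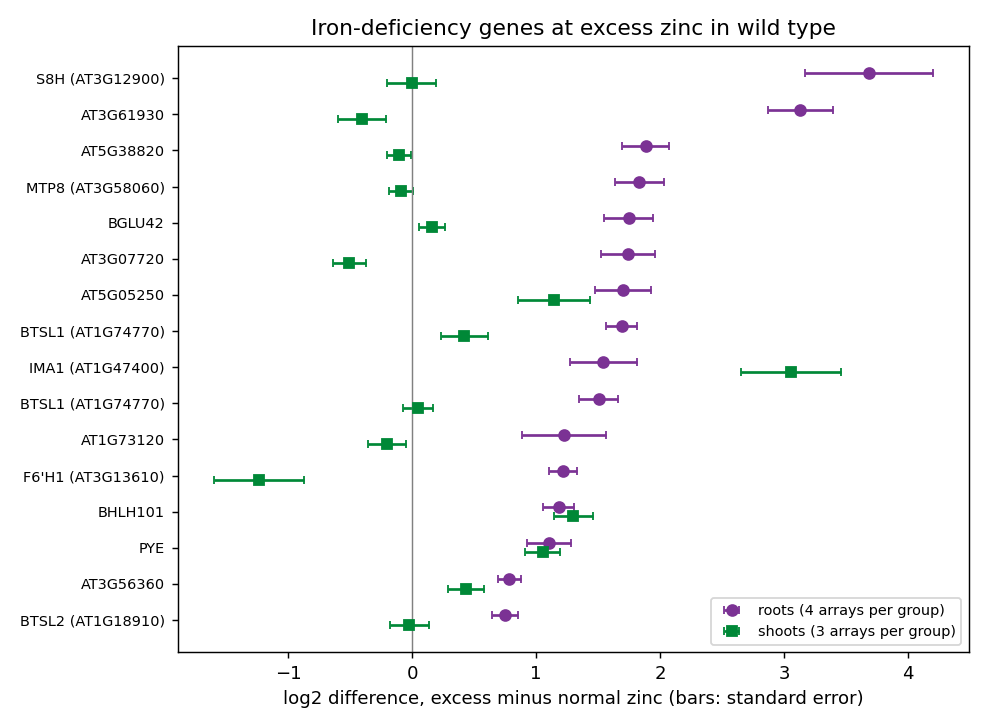
Log2 difference between excess and normal zinc in wild type for the measured genes of the iron deficiency lists, in roots (purple circles, 4 arrays per group) and shoots (green squares, 3 arrays per group), with standard errors as bars. In roots S8H lies highest, at 3.68, and in shoots IMA1, at 3.06, while S8H and MTP8 in shoots lie near 0.

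Outside the lists, large rises and falls in wild type roots at excess zinc were found for the genes below. The FAD-linked oxidoreductase gene AT1G26380 rose 9.98-fold (log2 difference 3.32, SE 0.39, adjusted p = 5.36e-06), the peroxidase genes AT5G64120 and AT1G49570 6.71-fold and 4.53-fold, the beta-glucosidase gene BGLU32 at least 6.09-fold and the glucosyltransferase gene UGT72E1 5.74-fold (SE 0.16, adjusted p = 1.4e-09). AT2G30660, AT4G34950 and AT2G30670 rose 5.62-fold, 4.61-fold and 4.18-fold. The 2-oxoglutarate-dependent dioxygenase genes AT1G52790, AT1G52820 and AT1G80320 fell 5.76-fold, 5.73-fold and 4.86-fold (log2 difference -2.53, SE 0.24, adjusted p = 3.99e-07 for AT1G52790), and AT3G13840 fell 4.00-fold. Smaller falls were those of AT3G59370 (3.27-fold), AT4G25250 (3.17-fold), the glutathione transferase gene GSTU26 (3.00-fold), UPB1 (2.86-fold), which encodes a bHLH repressor of peroxidase genes in roots, AT4G11210 and XTH16 (both 2.65-fold). CITF1 (AT1G71200) fell (log2 difference -0.78, adjusted p = 0.00467) and CCS rose 1.49-fold (adjusted p = 0.00883), each opposite in sign to its change at low zinc. In all 2206 probe sets changed, 1355 up and 851 down, 263 of them by at least 2-fold. Replicate 2 at excess zinc stood apart, with a mean correlation of 0.98 with the other arrays of its group, against 0.991 to 0.997 in the root arrays of other groups, and 1956 probe sets were called without it. The count was 674 from the arrays of these groups alone and 1418 from the arrays of this date, and the calls of the genes named by size held in both.

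Among the gene families tested in this comparison, 10 of 47 glycosyltransferase genes (UGT) rose and 1 fell (camera adjusted p = 0.000506, adjusted p = 0.47 with an estimated correlation), and 4 of 20 beta-glucosidase genes (BGLU) rose (camera adjusted p = 0.0115, adjusted p = 0.0924 with an estimated correlation). In the U-box family (PUB) 3 of 9 members rose (camera adjusted p = 0.019, adjusted p = 0.403 with an estimated correlation). Falls were found for 3 of 9 cell wall XTH genes (camera adjusted p = 0.019, adjusted p = 0.47 with an estimated correlation), 3 of 10 RALFL peptide genes (camera adjusted p = 0.0227, adjusted p = 0.47 with an estimated correlation) and 2 of 11 GSTU genes (camera adjusted p = 0.0227, adjusted p = 0.418 with an estimated correlation). Of the 14 nuclear photosynthesis genes 2 fell, PSAN by 1.3 and CHLM by 0.61 on the log2 scale (camera adjusted p = 0.0227, adjusted p = 0.505 with an estimated correlation). The call of PSAN (adjusted p = 0.0112), which also belongs to the markers of photosynthetic tissue, was lost without replicate 1 at normal zinc (log2 difference -0.984). Of the 4 markers it was the only one to pass, over all genes tested and adjusted over the list alone (camera adjusted p = 0.328). The 8 defensins did not pass, nor did any adjusted over the list alone (limma; camera adjusted p = 0.576).

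**Figure D3:**
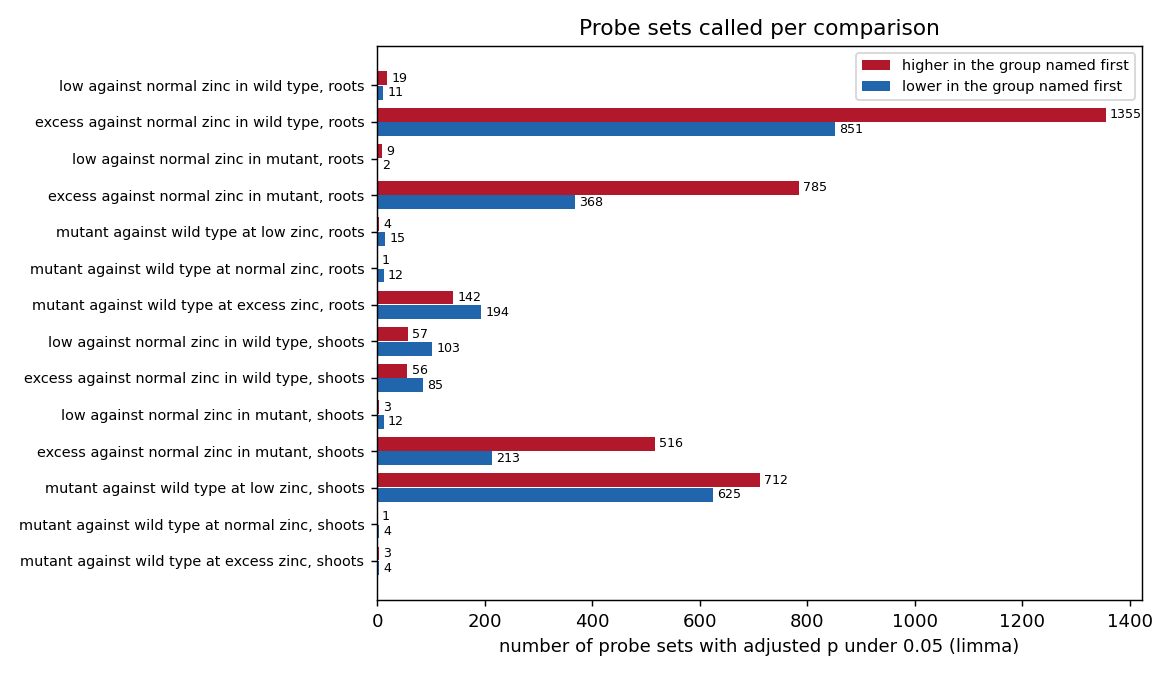
Number of probe sets called by limma (adjusted p under 0.05) in each comparison of a pair of groups within a tissue, higher (red) or lower (blue) in the group named first. The longest bars are those of excess against normal zinc in roots, with 1355 higher and 851 lower in wild type, and of mutant against wild type at low zinc in shoots, with 712 higher and 625 lower.

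Mutant roots responded to excess zinc with many of the genes that changed in wild type. All 9 iron deficiency genes rose, and 9 rose adjusted over the list alone (camera adjusted p = 2.96e-27, and adjusted p = 0.00024 with an estimated correlation), with S8H at 7.37-fold, IMA1 at 5.42-fold, MTP8 at 3.89-fold and BGLU42 at 2.57-fold. All 6 marker loci rose too (camera adjusted p = 8.34e-21, and adjusted p = 0.00024 with an estimated correlation), AT3G61930 by 9.39-fold and AT5G05250 by 4.42-fold. The iron deficiency list did not differ between the genotypes' responses (camera adjusted p = 0.415 for the interaction). AT1G52820 fell 4.39-fold, AT3G13840 4.00-fold, AT1G52790 3.87-fold, AT1G80320 3.49-fold and AT1G24420 2.38-fold, and AT3G48450 rose 7.41-fold (adjusted p = 0.00247). AT5G10040 (7.49-fold, adjusted p = 0.0401) and AT2G17850 (7.06-fold, adjusted p = 0.0447) also passed, but lost their calls without any of 7 of the 8 arrays. ZIP9 rose by 1.14 (log2, adjusted p = 3.54e-05). In all 1153 probe sets changed, 785 up and 368 down. Of these, 539 rose and 141 fell in both genotypes, against 46.8 and 13.8 expected of independent lists, and none changed in opposite directions. The count was 600 without mutant replicate 4 at excess zinc, 648 without mutant replicate 4 at normal zinc and 750 with the actin covariate.

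The response to excess zinc differed between genotypes for 3 root probe sets, that of AT3G59930 and AT5G33355, probe set A, which also passed at low zinc, and a further probe set D, also unnamed and chosen after its values were seen. Each fell in wild type and did not pass in mutant. The probe set of AT3G59930 and AT5G33355 fell 7.2-fold in wild type, from 11.49 ± 0.18 to 8.64 ± 0.66, and stood at 8.30 ± 0.39 and 8.33 ± 0.20 in mutant (SD, n = 4; interaction 2.88, adjusted p = 0.000121). The interactions were 2.16 for D (adjusted p = 1e-06) and 0.81 for A (adjusted p = 0.0488). Thus the probe set of AT3G59930 and AT5G33355 and A passed both tests of a genotype by zinc interaction in roots, with wild type means of 13.96, 11.49 and 8.64 and of 9.18, 7.56 and 6.79 at low, normal and excess zinc. The count was 31 without wild type replicate 4 at excess zinc and 8 from all 42 arrays. The call of A was lost in most alternatives, and the other 2 kept theirs in all.

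Between genotypes at normal zinc, roots differed in few probe sets. Besides bZIP19 and AT5G24240, AT5G38710 was 1.81-fold lower in mutant (log2 difference -0.85, SE 0.12, adjusted p = 0.00137), ATC was 2.23-fold lower (adjusted p = 0.0381) and Fes1C was 1.44-fold higher (adjusted p = 0.0379). The probe set of AT3G59930 and AT5G33355 was 9.12-fold lower (adjusted p = 1.32e-08). Of the unnamed probe sets, D was 14.8-fold lower (adjusted p = 1.84e-15; 29-fold at low zinc), B 3.03-fold, A 2.26-fold and C 1.64-fold. ATC and Fes1C lost their calls in several alternatives. In all 13 probe sets differed, 1 higher and 12 lower. The count was 24 without mutant replicate 2, 348 without wild type replicate 1 and 21 from all 42 arrays.

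At excess zinc more root genes were called between the genotypes. BGLU32 was at least 4.46-fold lower in mutant (log2 difference -2.16, SE 0.31, adjusted p = 0.00171), the peroxidase genes AT5G64120, AT1G14550 and AT5G39580 3.35-fold, 3.25-fold and 2.35-fold lower, the chitinase gene AT2G43620 2.38-fold and AT2G30660 2.37-fold lower, with NANA (2.32-fold) and AT1G26390 (at least 2.14-fold). UPB1 was 2.84-fold higher (log2 difference 1.51, SE 0.26, adjusted p = 0.00958), AT3G59370 2.60-fold, GSTU26 2.57-fold (adjusted p = 0.00468), AT1G12080 2.12-fold, AT1G62510 2.09-fold, AT4G25250 2.05-fold, XTH16 and AT3G10020 both 1.97-fold, AT4G28085 1.92-fold and AT4G22460 1.90-fold. The response to excess zinc itself did not pass the test of a difference between genotypes for BGLU32 (interaction -2.09, adjusted p = 0.186) or UPB1 (1.00, adjusted p = 0.659). The size for BGLU32 is uncertain, as its wild type mean at normal zinc, 4.01, may hold background. Of the 8 autophagy genes of the ATG family 1 was higher over all genes tested and 7 were higher adjusted over the list alone (camera adjusted p = 1.1e-06, but adjusted p = 0.267 with an estimated correlation). In all 336 probe sets differed, 142 higher and 194 lower. Of these, 84.5% had the same direction at normal zinc, on other root arrays of this date, against 60.8% of all probe sets. At low zinc in roots 35.4% did, against 50.4% of all probe sets. The genotype by excess zinc interaction called 3 probe sets, so the count alone does not show a difference particular to excess zinc. The count was 49, 140, 24 and 516 without mutant replicates 1, 2, 3 and 4, 50, 78 and 1305 without wild type replicates 1, 2 (the array of low correlation) and 4, 5 from the arrays of these groups alone, 46 from the arrays of this date, 141 with the actin covariate and 510 from all 42 arrays. BGLU32, GSTU26 and AT2G30660 lost their calls only from the arrays of these groups alone, where the same differences had adjusted p-values of 0.192, 0.268 and 0.263. Without mutant replicate 3 the calls of UPB1 (1.43), AT1G14550 (-1.555), AT5G64120 (-1.633) and AT3G59370 (1.34) were lost. Most of the other genes named lost theirs in several alternatives.

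In wild type shoots, low zinc lowered more genes than it raised. AT3G19680 fell 3.08-fold (log2 difference -1.62, SE 0.20, adjusted p = 0.000912, n = 3), the brassinosteroid-responsive gene EXO 2.83-fold (adjusted p = 0.00777), AT5G44020 and AT2G30930 2.66-fold and 2.63-fold, the transcription factor genes BZIP61 and AT5G61590 2.61-fold and 2.55-fold, AT2G16660 2.52-fold, ATPMEPCRB 2.48-fold and AT1G10020 2.2-fold. CCS fell 2.15-fold (log2 difference -1.10, SE 0.22, adjusted p = 0.0299) and AT3G15640 fell by 0.45 (log2, adjusted p = 0.0386), the pair that also fell in roots. The probe set of AT3G59930 and AT5G33355 rose 2.17-fold (adjusted p = 0.00734), a call lost without replicate 2 at normal zinc (0.97) and from the arrays of these groups alone (adjusted p = 0.177). In mutant it did not pass (0.29, adjusted p = 0.831), nor did the difference between the genotypes' responses (interaction -0.83, adjusted p = 0.94). Among the unnamed probe sets, A rose 4.83-fold in wild type shoots (adjusted p = 3.95e-08), C 2.04-fold and B 1.52-fold. PORB, an enzyme of chlorophyll synthesis among the 4 markers of photosynthetic tissue, fell 1.96-fold (SE 0.16, adjusted p = 0.00865) and was the only 1 to fall adjusted over the list alone (camera adjusted p = 0.134). AT1G77280 rose 2.09-fold, the ubiquitin ligase gene PUB19 2.01-fold (adjusted p = 0.00899), AT5G65320 1.79-fold, AT1G11410 1.72-fold, AT5G47800 1.69-fold, the cation exchanger gene CHX20 1.66-fold and AT3G16940 1.57-fold (adjusted p = 0.0041). The XTH family was lower as a list (camera adjusted p = 0.00446, but adjusted p = 0.269 with an estimated correlation), and the defensins did not pass (camera adjusted p = 0.676). In all 160 probe sets changed, 57 up and 103 down, 8 of them also called in the same direction in roots. Replicate 1 at low zinc stood apart in its control probe sets, with an actin 3' minus 5' signal of 6.116 against 1.289 to 1.948 in the other shoot arrays. The count was 77 without replicate 3 at low zinc, 96, 39 and 95 without replicates 1, 2 and 3 at normal zinc, 31 from the arrays of these groups alone, 89 from the arrays of this date and 435 from all 42 arrays. Without replicate 2 at normal zinc the calls of EXO (log2 difference -1.426), BZIP61 (-1.3), AT5G61590 (-1.33), PUB19 (0.958), PORB (-0.941) and CCS (-1.174) were lost, and CCS also lost its call without replicate 2 (-1.098) or 3 (-0.972) at low or replicate 1 (-0.851) at normal zinc. AT1G77280, AT5G65320, AT1G11410, AT5G47800, CHX20 and ATPMEPCRB lost theirs in several alternatives, while AT3G19680, AT5G44020, AT2G30930 and AT2G16660 kept theirs under every alternative.

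**Figure D4:**
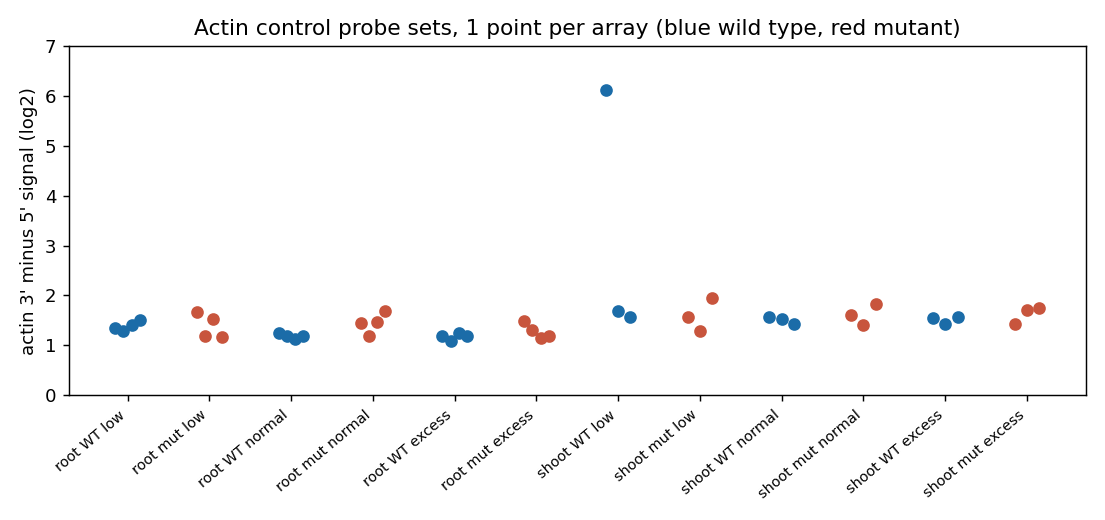
Difference between the 3' and 5' control probe sets of actin (log2) for each array, by group, with wild type in blue and mutant in red. Replicate 1 of wild type shoots at low zinc stands at 6.116, and the other shoot arrays between 1.289 and 1.948.

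Mutant shoots at low zinc changed in 15 probe sets, 3 up and 12 down. AT2G46150 rose 1.53-fold (log2 difference 0.61, SE 0.10, adjusted p = 0.0333), and TUB5 fell 1.73-fold, AT4G14230 1.61-fold, AT3G47160 1.55-fold and AT2G35470 1.42-fold. AT2G46150 was also the only named gene among the 3 probe sets whose response to low zinc differed between genotypes, with means of 7.54 in mutant at low, 6.93 in mutant at normal, 6.60 in wild type at low and 7.08 in wild type at normal zinc (interaction 1.09, SE 0.14, adjusted p = 0.00958). The others, chosen after their values were seen, were probe sets A (-2.23, adjusted p = 1.11e-05) and C (-1.03, adjusted p = 0.0235), which rose less in mutant than in wild type, as in roots. The call of C was lost in most alternatives. CCS did not pass in mutant shoots (log2 difference -0.68, adjusted p = 0.334). The count of 15 was 9, 5 and 4 without replicates 1, 2 and 3 at low zinc, 70, 6 and 4 without replicates 1, 2 and 3 at normal zinc, 89 without wild type replicate 1 at low zinc, 185 from all 42 arrays, and 0 from the arrays of these groups alone or of this date (limma; 1696 probe sets had an unadjusted p under 0.05 in the fit of all shoots). Another quantile normalisation gave 32 and centring of each array 34. Each of the 5 genes named lost its call without any 1 of the 3 arrays at low zinc. The interaction of AT2G46150 was lost without wild type replicate 2 at normal zinc (1.067), when the count of 3 was 1.

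Genes of the iron deficiency response also rose in shoots at excess zinc, but fewer of them. Of the 9 measured, 3 rose over all genes tested, and adjusted over the list alone 3 rose and 1 fell (camera adjusted p = 0.00114, and adjusted p = 0.039 with an estimated correlation). IMA1 rose 8.33-fold, from 7.33 ± 0.18 to 10.38 ± 0.77 (SD, n = 3; log2 difference 3.06, SE 0.40, adjusted p = 0.00135), BHLH101 at least 2.46-fold (adjusted p = 0.000553) and PYE 2.08-fold (adjusted p = 0.00155). Values that did not pass were F6'H1 (log2 difference -1.24, adjusted p = 0.18), S8H (0.00, adjusted p = 0.998) and MTP8 (-0.09, adjusted p = 0.848), and no marker locus passed (limma; camera adjusted p = 0.875). AT1G56300 rose 2.29-fold (SE 0.12, adjusted p = 0.000123) and AT3G15720 1.74-fold (adjusted p = 0.00641). BCAT4, of glucosinolate synthesis, rose 1.91-fold, AT2G39920 1.91-fold and DPE1 1.79-fold. The copper amine oxidase gene AT3G43670 fell 2.55-fold (log2 difference -1.35, adjusted p = 0.00713), UGT73D1 2.36-fold, EXO 2.35-fold, AT3G49160 at least 2.31-fold, AT1G68650 2.07-fold (adjusted p = 0.000488), LEA4-5 2.06-fold and AT2G46150 1.87-fold (adjusted p = 0.000272). The defensins did not pass (camera adjusted p = 0.875), and the XTH family was lower as a list (camera adjusted p = 0.00461, but adjusted p = 0.21 with an estimated correlation). In all 141 probe sets changed, 56 up and 85 down, of which 16 rose and 16 fell in roots too and 15 changed in opposite directions in the tissues. The groups lay on different array dates, and the count was 35 and 67 without replicates 2 and 3 at excess zinc, 60, 40 and 85 without replicates 1, 2 and 3 at normal zinc, 223 with the actin covariate and 369 from all 42 arrays. IMA1, BHLH101, PYE, AT1G56300, AT3G15720, AT1G68650 and AT2G46150 kept their calls under every alternative applied to them, the fold of at least 2 left aside. AT3G43670 lost its call without replicate 2 at excess zinc (-1.25), as did UGT73D1 (-1.049), EXO (-1.18) and BCAT4 (0.846). AT3G49160, LEA4-5, AT2G39920 and DPE1 lost theirs in several alternatives.

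In mutant shoots at excess zinc IMA1 rose 6.67-fold (log2 difference 2.74, adjusted p = 0.00305), BHLH101 at least 2.2-fold and PYE 1.94-fold, again 3 of the 9 iron deficiency genes, while adjusted over the list alone 4 rose and 2 fell (camera adjusted p = 0.101). AT1G56300 rose 4.59-fold (log2 difference 2.2, SE 0.12, adjusted p = 3.37e-08), AT4G30650 3.28-fold, AT4G30660 2.67-fold and AT2G43550 2.64-fold. The chloroplast gene atpH fell 3.21-fold (adjusted p = 0.0349), CML41 3.14-fold, AT3G28510 3.06-fold, AT3G43670 2.66-fold and AT3G49160 at least 2.53-fold. CCS rose by 1.01 (log2, adjusted p = 0.0244). In all 729 probe sets changed, 516 up and 213 down, of which 39 rose and 33 fell in wild type too, against 1.3 and 0.8 expected of independent lists. Excess and normal zinc lay on different array dates in both genotypes, so a date effect would give shared calls too. No probe set passed the test of a difference between the genotypes' responses (limma, 0 called; 1844 had an unadjusted p under 0.05). The share of calls that were rises was 70.8%, but 54.3% after another quantile normalisation and 52.9% after centring each array. The count was 235, 124 and 389 without replicates 1, 2 and 3 at excess zinc, 396, 260 and 335 without replicates 1, 2 and 3 at normal zinc, 1223 without wild type replicate 1 at low zinc, 425 from the arrays of these groups alone, 1328 with the actin covariate and 1412 from all 42 arrays. AT1G56300, IMA1, AT4G30650, AT3G43670 and AT3G49160 kept their calls under every alternative, while atpH, CML41 and CCS lost theirs in several. Without replicate 2 at excess zinc AT4G30660 (1.256), AT2G43550 (1.328) and AT3G28510 (-1.38) lost theirs.

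At low zinc, shoots differed widely between genotypes. Besides bZIP19 and AT5G24240, AT2G44240 was 6.88-fold higher in mutant (log2 difference 2.78, SE 0.47, adjusted p = 0.00559, n = 3; 10.8-fold without mutant replicate 1), AT1G68620 3.37-fold (adjusted p = 0.00353), AT3G28510 2.93-fold, AT1G65690 2.60-fold (adjusted p = 0.00144), the invertase gene cwINV6 2.60-fold, the chitinase gene CHI (AT2G43570) 2.60-fold, UGT73D1 2.59-fold and AT3G26440 2.57-fold. AT3G45160 was 2.75-fold lower, the chalcone isomerase-like gene CHIL and QQS 2.55-fold, AT4G33960 2.5-fold, CSLA01 2.45-fold and the cold-regulated gene COR15A 2.26-fold. Of the 8 defensins 1 was higher, PDF1.4 (log2 difference 0.58, adjusted p = 0.0124), and 1 lower, PDF2.3 (-0.79, adjusted p = 0.0474), with the same 2 adjusted over the list alone, and the list did not pass (camera adjusted p = 0.615). In all 1337 probe sets differed, 712 higher and 625 lower, 139 of them by at least 2-fold. Wild type replicate 1 had the actin 3' minus 5' signal of 6.116, and the group means of that signal were 3.12 in wild type and 1.60 in mutant. The count was 85 and 438 without mutant replicates 2 and 3, 897 without wild type replicate 1, 844 with the actin covariate, 44 from the arrays of these groups alone and 2352 from all 42 arrays. AT1G68620, AT1G65690, UGT73D1 and AT3G26440 kept their calls under every alternative, while without mutant replicate 2 those of AT2G44240 (2.34), AT3G28510 (1.267), AT3G45160 (-1.322), CHIL (-1.138), COR15A (-1.165), CHI (1.216), QQS (-1.004), AT4G33960 (-1.119), CSLA01 (-1.074), PDF1.4 (0.552) and PDF2.3 (-0.618) were lost.

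**Figure D5:**
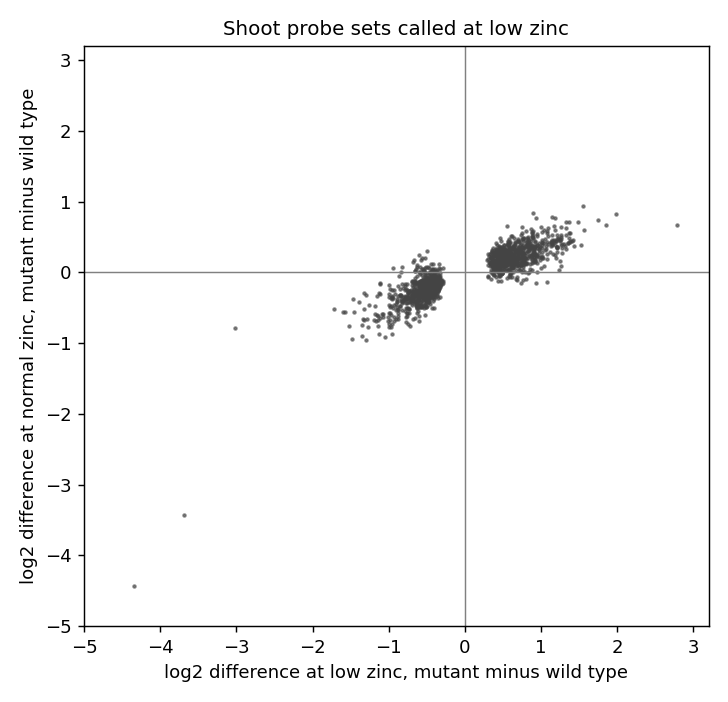
Log2 difference between mutant and wild type shoots at normal zinc (vertical axis) against that at low zinc (horizontal axis) for the 1337 probe sets called at low zinc, 1 point each. Of these points, 93.9% have the same sign at both supplies, most of them closer to 0 at normal zinc, which choosing them by their low zinc values would also give.

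At normal zinc the shoots of mutant and wild type differed in 5 probe sets and at excess zinc in 7. AT1G08940 was higher in mutant at all supplies, 1.80-fold at normal zinc (log2 difference 0.84, SE 0.13, adjusted p = 0.0333), 2.32-fold at excess zinc (1.21, adjusted p = 0.000274) and by 0.89 on the log2 scale at low zinc (adjusted p = 0.00318). At excess zinc AT1G56300 (1.97-fold, adjusted p = 0.00151) and AT5G52390 (1.99-fold) were also higher and AT1G18485 was 1.58-fold lower (adjusted p = 0.00695). The chloroplast-encoded genes were lower in mutant at excess zinc as a list, with 42 of 43 values below 0 and no member called (camera adjusted p = 6.74e-05, but adjusted p = 0.785 with an estimated correlation). The call of AT1G08940 at normal zinc was lost without any 1 of the 6 arrays, when the count of 5 was 2, 3, 2, 2, 2 and 2, and all 42 arrays gave 37. At excess zinc the count of 7 was 4 without wild type replicate 2, 11 without wild type replicate 1 at low zinc, 12 with the actin covariate and 24 from all 42 arrays. AT5G52390 and AT1G18485 lost their calls without several single arrays.

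Roots against shoots gave the most calls of the 21 comparisons. In wild type at normal zinc, AT4G39675 was 348-fold and AT1G19530 at least 343-fold higher in roots than in shoots, as were AT4G33720 (270-fold) and the peroxidase genes AT3G01190 (255-fold) and AT4G30170 (at least 245-fold). AT1G09310 was at least 448-fold lower, AT2G41090 at least 355-fold, ECS1 296-fold, the photosystem I gene PSAE-1 243-fold and PRK of the Calvin cycle 233-fold (log2 difference -7.87, SE 0.10, adjusted p = 3.19e-38). All 4 markers of photosynthetic tissue (RCA, PSAN, PORB and PRK) were lower in roots, and 4 were lower adjusted over the list alone (camera adjusted p = 1.87e-06, and adjusted p = 0.00048 with an estimated correlation), as were the 14 nuclear photosynthesis genes (camera adjusted p = 2.95e-19, and adjusted p = 0.00048 with an estimated correlation). The 43 chloroplast-encoded genes were lower too (camera adjusted p = 1.34e-17, but adjusted p = 0.15 with an estimated correlation). Both measured root markers were higher in roots, PYK10 77.2-fold (adjusted p = 1.83e-20) and the root hair expansin gene EXPA7 5.32-fold (adjusted p = 1.65e-11). Of the 8 defensins 4 were higher in roots, PDF2.5 by at least 23.7-fold and PDF2.1 by at least 8.78-fold among them, and 2 were lower, PDF1.2A by at least 112-fold and PDF1.2B by 33.4-fold, with 4 higher and 3 lower adjusted over the list alone (camera adjusted p = 0.925). In all 13838 probe sets differed, 8103 higher and 5735 lower in roots. Tissue and array date cannot be told apart here.

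The response to low zinc differed between tissues for AT1G71200, which rose in roots and stood at 0.10 (log2 difference, adjusted p = 0.835) in shoots (interaction 1.59, SE 0.23, adjusted p = 0.000304). AT5G61590 (1.58, adjusted p = 0.0103), BZIP61 (1.4), EXO (1.33, adjusted p = 0.015) and AT5G25280 (1.27) had the higher value in roots, and CHX20 (-0.89, adjusted p = 0.0096) and AT1G77580 (-0.84) the lower. ZIP9 did not pass (0.71, adjusted p = 0.211). In all 92 probe sets differed. Low and normal zinc lay on different array dates in roots and on the same date in shoots. A date effect in roots therefore cannot be told apart from a difference between tissues here. The count was 49, 40 and 46 without root replicates 1, 2 and 4 at low zinc, 56 and 44 without root replicates 2 and 3 at normal zinc, 48 without shoot replicate 3 at low zinc and 21 without shoot replicate 2 at normal zinc. AT1G71200 kept its call under every alternative, while without shoot replicate 2 at normal zinc BZIP61 (1.312), EXO (1.258), AT5G25280 (1.207), CHX20 (-0.795) and AT1G77580 (-0.705) lost theirs, and AT5G61590 (1.217) did without shoot replicate 3 at low zinc.

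The response to excess zinc differed between tissues for 6 of the 9 iron deficiency genes, with 6 higher and 1 lower in roots adjusted over the list alone (camera adjusted p = 5.94e-08, and adjusted p = 0.017 with an estimated correlation) and 4 of the 6 marker loci (camera adjusted p = 5.04e-11, and adjusted p = 0.00312 with an estimated correlation), with the stronger rise in roots. S8H (AT3G12900) had an interaction of 3.69 (SE 0.65, adjusted p = 0.000364; 3.075 without root replicate 1 at normal zinc) and AT3G61930 of 3.54 (adjusted p = 7.46e-08). AT1G26380 (3.92, adjusted p = 7.11e-06), BGLU32 (2.58), AT2G30660 (2.52) and ZIP9 (0.99, adjusted p = 0.00752) also rose more in roots. The size for BGLU32 is uncertain, as its root mean at normal zinc, 4.01, lay above only 2.9% of the probe sets. AT1G52820 (-2.57), AT1G52790 (-2.52), AT1G80320 (-2.51), AT3G13840 (-1.73) and GSTU26 (-1.67) had the lower value in roots. In all 1048 probe sets differed, 785 higher and 263 lower. Excess and normal zinc lay on different array dates in shoots and on the same date in roots. A date effect in shoots therefore cannot be told apart from a difference between tissues here. The count was 590 without shoot replicate 2 at excess zinc and 541 from the arrays of these groups alone, where ZIP9 (adjusted p = 0.0879) and GSTU26 (adjusted p = 0.0501) lost their calls.

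Other lists had only 1 or 2 measured members. In wild type roots at excess zinc, SDI2 (AT1G04770) of the sulfate starvation list rose 1.43-fold (log2 difference 0.52, adjusted p = 0.0275) and the clock gene GI 1.46-fold (0.55, adjusted p = 0.00483). GSTU25, of the detoxification list, rose 1.55-fold in mutant roots (adjusted p = 0.032). SDI2 and GSTU25 lost their calls in several alternatives, and GI in wild type lost its call only from the arrays of these groups alone (adjusted p = 0.0722). In wild type roots the zinc transporter gene ZIP6 stood at 0.33 (log2 difference, adjusted p = 0.238) at low and -0.07 (adjusted p = 0.769) at excess zinc, and the zinc efflux gene MTPA1 at 0.15 (adjusted p = 0.594) and 0.12 (adjusted p = 0.38). The metallothionein gene MT1C of the chelation list stood at 0.03 (adjusted p = 0.961) and -0.18 (adjusted p = 0.128). At excess zinc EXPA7 stood at -0.47 (adjusted p = 0.277) and EXPA18 at -0.34 (adjusted p = 0.561). Between tissues, ZIP6 was 2.53-fold, MT1C 5.99-fold and EXPA18 6.41-fold higher in roots, and BGLU28 at least 2.03-fold, DFR of anthocyanin synthesis 42.1-fold and UF3GT 10.2-fold lower.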

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

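The tests of degraded RNA, of the array date, of the part of the low zinc response that needs bZIP19 and bZIP23, of zinc acting on AT5G24240 and of the interactions by reassigned residuals were chosen only after the result was seen, and the other tests below before it.

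The genotypes differed most in shoots at low zinc, with 1337 probe sets called against 5 at normal and 7 at excess zinc. Degraded RNA on wild type replicate 1, whose actin control stood out at 6.116, is argued against as the source of all these calls, since 897 were called without that array, 646 of them among the 1337, although part of the calls may rest on it. A difference of these 6 arrays alone is argued against by the other arrays of that date, since 93.9% of the called probe sets had the same direction at normal zinc, against 64.3% of all probe sets. At excess zinc, on another date, 66.1% had the same direction, against 51.4% of all probe sets, but the median difference was 0.08 against 0.58 where called, and in roots 74% had the same direction at low, 58% at normal and 33.5% at excess zinc, against 60.4%, 53.6% and 45.4% of all probe sets, so that a difference of like size at every supply is not shown. Whether the difference is larger at low zinc stays open, because the count fell to 85 without mutant replicate 2 and the test of a genotype by low zinc interaction called 3 probe sets. The 1337 were also chosen by their values at low zinc, which by itself makes their differences at other supplies smaller.

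The 30 probe sets called at low zinc in wild type roots lay on another array date than their controls. A date effect is argued against for 8 of them, which were called in the same direction in wild type shoots, where both groups share a date, against 0.0974 expected of independent lists. The argument holds for the set more than for each of the 8. CCS lost its root call without any of the 8 arrays compared. In shoots CCS, B and the probe set of AT3G59930 and AT5G33355 lost theirs without replicate 2 at normal zinc, while A and C kept theirs. The shoot calls of the rest of the 8, AT3G15640 and unnamed probe sets, were not followed in that setting. Far fewer shoot probe sets were called there in all, so how many of the 8 would remain is not known. A constant date effect could not give the smaller response in mutant of 4 of the 30, which passed the interaction test, although that test shares its wild type arrays with the comparison itself. For the remaining probe sets the date and the zinc supply cannot be told apart, since 14 of these 22 (63.6%; 73.3% of all 30) had the same direction in shoots, against 52.7% of all probe sets, and no root groups of both supplies share a date. A response to zinc deficiency, part of it through bZIP19 and bZIP23, is therefore a hypothesis for those that passed these tests.

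AT5G24240 was lower in mutant than in wild type at every supply in both tissues. Zinc supply acting on it through bZIP19 and bZIP23 is argued against, since the largest of its 4 interactions was 0.43 in size on the log2 scale (adjusted p = 0.643), beside genotype differences of -3.22 to -3.72. A lesion that spans its neighbourhood could be judged from only 3 of 20 neighbouring genes. Their 6 median differences ran from -0.007 to 0.245, and the lowest single value was -0.115. This argues against a lesion that lowers these 3 genes, but leaves open one that reaches only neighbours not measured. A second lesion within AT5G24240, and a dependence on the pair of factors that zinc does not alter, may each account for it and were not tested.

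Among groups of 4 root arrays, 12 of 165 held a value far from the other 3, where 1 in 20 groups, or 8.2, would by chance. The measure is the gap to the nearest value divided by the range of the group. In wild type at normal zinc replicate 1 it was 0.838 for CCS (9.97 against 9.38 to 9.48), 0.862 for AT3G12900 (6.02 against 8.3 to 8.66), 0.876 for AT3G61930 (6.27 against 7.24 to 7.38) and 0.939 for AT1G49570 (8.46 against 9.63 to 9.7). At low zinc in wild type replicate 3 it was 0.876 for AT3G44840 (7.5 against 7.81 to 7.86) and 0.936 for AT5G24240 (10.34 against 10.08 to 10.1). At excess zinc in wild type it was 0.843 for AT4G25250 in replicate 4, 0.857 for AT4G11210 in replicate 3 and 0.938 for AT5G24240 in replicate 2. In mutant it was 0.957 for bZIP19 in replicate 3 at normal zinc (4.75 against 4.35 to 4.37), and 0.877 for AT4G28085 and 0.837 for BGLU32 in replicate 4 at excess zinc.

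Responses differed between groups, by the interaction tests, for 4 probe sets in roots at low zinc and 3 at excess zinc, for 3 in shoots at low zinc, of which AT2G46150 (1.09, log2) was named, and between tissues for 92 probe sets at low and 1048 at excess zinc. The control probe sets, which no comparison used, set wild type shoots at low zinc replicate 1 apart, as degraded RNA could. Besides actin, the 3' minus 5' signal of GAPDH stood at 1.893 against 0.012 to 0.495 in the other shoot arrays, and that of ubiquitin at 0.982 against 0.273 at most. The poly-A spike-in controls stood at 6.67, against 8.276 to 9.367 in the other shoot arrays. Whether the RNA itself was degraded was not tested.

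Of the 35 splits of the root arrays into groups of the same size, only the real one gave as many calls in several comparisons. These were low zinc in wild type (30 called, highest other 0), excess zinc in wild type (2206, highest other 150), excess zinc in mutant (1153, highest other 4) and mutant against wild type at low zinc (19, highest other 0). Chance is less likely there but not excluded. A share of 1 in 35 is the smallest possible and was not adjusted for the number of comparisons. Other splits mix the real groups, which adds the real difference to their spread and lowers their counts. For low zinc in wild type a date effect would set the real split apart as well. For low zinc in mutant roots 2 of 35 splits gave as many (11, highest other 13). The same held for the genotypes at normal zinc (2 of 35; 13, highest other 943) and at excess zinc (2 of 35; 336, highest other 382). The splits do not argue against chance in these comparisons. A split that calls 943 probe sets where the real groups call 13 may point to a structure of these arrays that the groups do not describe, which was not tested. For the shoot comparisons the 10 splits are too few: the real split gave 160, 141, 15 and 729 for low and excess zinc in wild type and in mutant and 1337 and 5 for the genotypes at low and normal zinc, each with a highest other of 0 and 1 split as large, and 7 for the genotypes at excess zinc, with a highest other of 1.

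For the interactions, the residuals of the fit without the interaction were reassigned among the arrays at random, which keeps the responses shared by both genotypes or tissues. Each share is out of 100 cases, of which the real arrangement is 1. Only the real arrangement gave as many calls (1 of 100) for the genotype by low zinc interaction in roots (4 called, highest other 1). The same held for the tissue by low zinc interaction (1 of 100; 92, highest other 65) and the tissue by excess zinc interaction (1 of 100; 1048, highest other 559). Chance is unlikely in these, but a date effect could set the real arrangement apart as well in the tissue interactions. As many calls came in 4 of 100 cases, the real one included, for the genotype by excess zinc interaction in roots (3, highest other 250) and for the genotype by low zinc interaction in shoots (3, highest other 401). That is narrowly under 1 in 20, and the few reassignments with many times the real count may point to a structure of the samples, which was not tested. For shoots at excess zinc 0 were called by limma (1844 at an unadjusted p under 0.05, highest other 1), so that all 100 gave as many by construction and the count says nothing about chance. This test replaced reassignments of the zinc labels within each genotype, which turn a shared zinc response into an interaction and had given as many calls in 10, 6 and 6 of 100, the real labels included, for the same 3 genotype interactions. For roots against shoots only the real split gave as many calls (1 of 35 splits; 13838, highest other 11718).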

How the results depend on the processing

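The fits of 1 array date only, the actin covariate, the fits without an array outside the groups compared and the list tests without the 2 arrays of doubtful quality were chosen only after the data were seen, and the other settings before. No result reversed under any setting. For genes named by size between a pair of groups this was partly fixed in advance. Their values did not overlap, so leaving out an array could not reverse them, and settings that change only the estimated spread keep the sign. Of 193 named results of single genes, 86 kept their call under every setting applied to them, 107 lost it under at least 1 and 94 under at least 1 array left out. The fold of at least 2 was not applied to these results, and the fit without the third of lowest mean held 178 of the 193. The replicate number, which does not pair the samples (same-number pairs had a median correlation of -0.048 in roots and 0.008 in shoots), moved no count by more than 1.5 times as a block. The cause of the moves below was not tested, except that fewer arrays leave fewer degrees of freedom and that a fold of at least 2 counts fewer probe sets by construction. Array signal near the background limits weak genes, and without the third of lowest mean only the count at low zinc in mutant shoots moved, to 29.

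Only the arrays of the groups compared gave, for roots, 164 at low and 674 at excess zinc in wild type and 5 between genotypes at excess zinc, for shoots, 31 at low zinc in wild type, 0 at low and 425 at excess zinc in mutant, 44 at low and 3 at normal zinc between genotypes and 1 for the genotype by low zinc interaction, and 541 for the tissue by excess zinc interaction. Only the arrays of 1 date gave 1418 at excess zinc in wild type roots, 46 between genotypes in roots at excess zinc, 89 and 0 at low zinc in wild type and mutant shoots (limma; 1696 in mutant at an unadjusted p under 0.05 with all shoots), and 2 between genotypes in shoots at normal zinc. All 42 arrays in 1 fit gave, for roots, 70 in wild type and 39 in mutant at low zinc, 21 and 510 between genotypes at normal and excess zinc and 8 for the genotype by excess zinc interaction, and for shoots 435 and 369 in wild type and 185 and 1412 in mutant at low and excess zinc, 2352, 37 and 24 between genotypes at low, normal and excess zinc and 8 for the genotype by excess zinc interaction. Low zinc in mutant shoots gave 32 after another quantile normalisation, 34 after centring and 23 with trend and robust settings, which gave 3 between genotypes in shoots at normal zinc. The actin covariate gave 750 at excess zinc in mutant roots, 141 between genotypes in roots at excess zinc, 223 at excess zinc in wild type shoots, 96 and 1328 at low and excess zinc in mutant shoots, and 844 and 12 between genotypes in shoots at low and excess zinc.

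A fold of at least 2 was met in roots by 9 and 263 probe sets in wild type and 3 and 213 in mutant at low and excess zinc, and by 12 and 46 between genotypes at low and excess zinc. In shoots it was met by 39 and 39 in wild type and 4 and 79 in mutant at low and excess zinc, and by 139, 2 and 4 between genotypes at low, normal and excess zinc. Between tissues it was met by 5752, and by 31 and 365 for the interactions with low and excess zinc. An estimated correlation left 9 of the 80 list calls in 735 tests, while a replicate block gave 81, the mean of a gene's probe sets 79 and the fit without the 2 arrays of doubtful quality 77.

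Without 1 array of the groups compared, counts in roots ran from 15 to 66 for low and 1545 to 2915 for excess zinc in wild type, from 5 to 31 and 600 to 1135 in mutant, from 14 to 21, 11 to 348 and 24 to 1305 between genotypes at low, normal and excess zinc, and from 3 to 5 and 2 to 31 for the interactions of genotype with low and excess zinc. In shoots they ran from 39 to 153 and 35 to 206 in wild type, from 4 to 70 and 124 to 396 in mutant, from 85 to 1889, 2 to 3 and 4 to 7 between genotypes, and from 1 to 4 and 0 to 2 for the interactions. Between tissues they ran from 12969 to 13585, from 21 to 131 for the interaction with low zinc and from 590 to 1276 for that with excess zinc. Arrays outside the groups compared moved some counts too: 78 at low zinc in wild type roots and 21 in mutant roots without wild type replicate 2 at excess zinc, and 89, 1223 and 11 at low and excess zinc in mutant shoots and between genotypes at excess zinc without wild type shoot replicate 1 at low zinc.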

Other observations

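The lists of chloroplast-encoded genes and the gene families described here were chosen only after it was known which genes were measured. The 43 chloroplast-encoded photosynthesis genes moved as a list in several comparisons, with at most 1 member called in any comparison within a tissue. In shoots their mean was 9.69 ± 0.41 in wild type and 10.03 ± 0.49 in mutant at normal zinc and 10.01 ± 0.08 and 9.65 ± 0.26 at excess zinc (SD, n = 3), and their response to excess zinc was lower in mutant as a list, with a median interaction of -0.63 on the log2 scale and no member called (camera adjusted p = 1.02e-06, but adjusted p = 0.547 with an estimated correlation). In wild type roots at low zinc 35 of the 43 had values above 0 against normal zinc, with none called over all genes tested and 10 called over the list alone (camera adjusted p = 1.41e-06, but adjusted p = 0.646 with an estimated correlation). Neither call held with an estimated correlation.

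Of the 8 autophagy genes of the ATG family none was called at low zinc in wild type roots, over all genes tested or over the list alone, with a median log2 difference of 0.314 (camera adjusted p = 0.000321, but adjusted p = 0.646 with an estimated correlation). At excess zinc 1 of the 8 fell, with a median of -0.297 (camera adjusted p = 0.0297, but adjusted p = 0.571 with an estimated correlation). In wild type shoots at excess zinc none of the 12 UBP genes, for ubiquitin-specific proteases, was called, with a median log2 difference of 0.107 (camera adjusted p = 0.00405, but adjusted p = 0.426 with an estimated correlation). In the root response to excess zinc, no interaction of the 8 defensins with genotype was called, with a median of 0.228 (camera adjusted p = 0.0337, but adjusted p = 0.36 with an estimated correlation).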
